A study of Mus musculus with 8 samples.

How the data were processed

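Thoracic perivascular fat, the adipose tissue around the thoracic aorta, was profiled in 8 samples, 4 labelled RictoraP2KO and 4 labelled control. Per the labels' protocols the mice were male, 17 to 22 weeks old, fasted overnight and killed at 9 am, and 5 µg of total RNA entered the labelling. Each sample was hybridised to 1 Affymetrix Mouse Gene 1.1 ST array, whose probe sets are designed along the length of a transcript. The authors deposited 1 table of log2 values, 1 value for each of 28371 probe sets and 8 arrays, made with RMA (background correction, quantile normalisation and summarisation of the probes of a set) in Affymetrix Power Tools 1.10.2, per the submitters' processing notes. The deposited log2 values ran from 1.04 to 12.5, and after sorting each array no rank differed by more than 0.03 between arrays, with a median of 3.76 in every array. Quantile normalisation within RMA acts on probes before they are summarised, so it does not by itself force equal probe set values. With values this equal, a difference in total RNA output between the groups would not be seen, and normalising them again could move little. A total of 456 rows repeated the values of another row exactly. Correlations between arrays, across probe sets, lay between 0.989 and 0.995, and no 2 arrays were identical. Scanner intensities and scan dates were not used here.

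Probe sets were named from the platform annotation. It gave 1 gene symbol for 21158 probe sets, several for 1881 and none for 5332, and no gene was named from a probe set with several. This left 18782 genes, of which 1368 had more than 1 probe set; each gene was represented by its probe set with the highest mean over the 8 arrays. The clock genes Nr1d1 and Dbp share their probe sets with other genes in that annotation and were not analysed here. Gene order along chromosomes came from the RefSeq annotation of assembly GRCm38.p6; the build behind the array annotation is not given in the sources used here, so no coordinates are printed.

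The comparison was RictoraP2KO minus control. Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 28371 probe sets and a threshold of 0.05. No probe set was filtered out and no covariate was fitted. A total of 34 gene lists, of pathways and of cell types that this tissue could hold, were written before the data were examined, and 598 of their 671 entries had a probe set of their own. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with adjustment over the 34 lists. Camera asks whether the differences of a list's genes are on balance higher or lower than those of other genes. Genes that move in opposite directions therefore cancel. Camera with a correlation estimated from the arrays, and fry, were run as alternatives; fry asks whether the genes of a list move on balance one way, and its second p whether they move in either direction. A list mean per array was the mean over its genes of the log2 value minus that gene's mean over the 8 arrays. Intervals are at the 95% level. Single values were compared by an exact two-sided permutation test over the 70 assignments of 4 labels to 8 arrays, whose smallest possible p is 0.0286.

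The rule for the genes named was written before the data were examined. It takes Rictor; in each direction up to 12 genes with adjusted p under 0.05 and no overlap between the groups, by size of difference, filled to 10 by unadjusted p where fewer passed; every measured core clock gene; and in each other list up to 4 members past the threshold or otherwise up to 3 by unadjusted p. Predicted and unnamed gene models, small RNAs, and olfactory, vomeronasal and immune receptor segments were left out of the part that takes genes by direction. The lung genes Sftpc, Sftpb and Cyp2f2, of a list added later, and Pqlc3 were named outside this rule, after their values were seen.

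The tests were run on simulated data with the means and spreads of the real probe sets. For RictoraP2KO against control, with 4 and 4 simulated arrays, 28371 probe sets and 200 changed, limma recovered 48.2% of changes of 0.5 on the log2 scale, 89.4% of changes of 1 and 98.1% of changes of 2, as means over 10 runs. A sterol synthesis list lowered by 0.2 was called in 100% of 10 runs. Genes varied independently in this simulation, unlike in tissue. The number of arrays limits the precision, and since each label names a separate sample without saying that each is a separate animal, p-values measure the spread between these samples.

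Alternatives fixed beforehand were a filter on dim probe sets (mean under the median), quantile normalisation once more, median centring, limma-trend, robust eBayes, array weights, the replicate number as a block, each array left out in turn, an adjusted p under 0.1, an unadjusted p under 0.01 with a 1.5-fold difference, an adjusted p under 0.05 with a 1.5-fold difference, only probe sets with 1 symbol, an unmoderated test with equal variances, and the mean over all probe sets of a gene for the lists. Added after the data were seen were the joint omission of 3 arrays that carried marker signal of another tissue (RictoraP2KO replicate 2, control replicate 2 and control replicate 3) and 3 further lists: lung epithelium, clock genes that peak with or after Bmal1, and clock genes driven by E-boxes. The effect of the 3 arrays with signal of another tissue on the clock genes was first measured on the 7 with an unadjusted p under 0.05; as these had been picked for their differences, all 22 members were used in their place.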

Results

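Gene expression was measured in thoracic perivascular fat of mice labelled RictoraP2KO and of control mice, with 4 arrays in each group. Rictor is the subunit that defines mTOR complex 2, a kinase complex that phosphorylates Akt downstream of insulin. The knockout was driven by Cre recombinase under the promoter of aP2 (Fabp4), which is active in fat cells. Per the series title, the question was how loss of Rictor in fat and brain affects the expression of clock genes. Values are log2 RMA signals, given as mean ± SD (n = 4 arrays per group), and differences are RictoraP2KO minus control on the log2 scale with their standard error (SE). The number of arrays limits their precision.

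The Rictor signal was not lower in the arrays labelled RictoraP2KO. It was 6.68 ± 0.08 (SD, n = 4) there and 6.54 ± 0.06 (SD, n = 4) in the arrays labelled control, a difference of 0.14 (SE 0.063; limma adjusted p = 0.685), against the direction of the label. An exact two-sided permutation test gave p = 0.0571. The labels do not say which exons were deleted and the positions of the probes of this set (10422781) were not examined, so it is not known whether this signal could show the deletion. Every direction below therefore rests on the labels of the arrays and not on the Rictor signal. Of the other measured members of the list of mTOR complex genes, Mtor, the kinase itself, differed by -0.35 (SE 0.155) and Telo2, which helps to fold it, by -0.19 (SE 0.093). Neither passed the test, and the list of 11 genes was not called (camera adjusted p = 0.313).

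Across the array, 1 gene differed between the groups. Myt1l, a transcription factor of neurons, was higher in all 4 arrays labelled RictoraP2KO, at 3.66 ± 0.12 (SD, n = 4) against 2.68 ± 0.10 (SD, n = 4) in the control arrays. The difference was 0.99 (SE 0.080) (limma adjusted p = 0.0198), and no fold is given because both levels lay below the array median of 3.76. No other probe set of the 28371 passed, the next adjusted p being 0.116. At an unadjusted p under 0.05 there were 2062 probe sets, 1091 higher and 971 lower, where 1419 were expected by chance if probe sets varied independently. Splits of the 8 arrays into 4 and 4 that mixed the groups gave as many as 2861, so this excess does not separate the groups. The Myt1l call was lost when RictoraP2KO replicate 3 or 4 or any 1 of the 4 control arrays was left out. The limma adjusted p then ran from 0.0862 to 0.179. It was also lost without the 3 arrays that carried signal of another tissue, with the replicate number as a block, and in an unmoderated test. Without dim probe sets, a filter that removes Myt1l, 0 probe sets passed. Over the 8 omissions of 1 array the Myt1l difference stayed between 0.94 and 1.03. Without RictoraP2KO replicate 1, 5 probe sets passed.

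The 9 other genes with the smallest unadjusted p among those higher in the arrays labelled RictoraP2KO did not pass the adjusted threshold. Trdn, which encodes triadin of the muscle calcium release complex, stood at 6.57 ± 0.28 (SD, n = 4) against 5.32 ± 0.17 (SD, n = 4), a difference of 1.26 (SE 0.142; limma adjusted p = 0.116). All 19 Trdn probe sets had the same sign, with a median difference of 0.34. Of these, 7 had an unadjusted limma p under 0.05 and 4 had no overlap between the groups. Without RictoraP2KO replicate 1 the gene passed (limma adjusted p = 0.0126). Nrip1, a corepressor of nuclear receptors that restrains oxidative genes in fat, differed by 0.53 (SE 0.090) and the nuclear receptor gene Nr2f1 by 0.44 (SE 0.079). Arntl, described with the clock genes, was also among them. The remaining differences were 0.32 for Speer4a, 0.31 for Sema6d, 0.28 for Nfatc4, 0.29 for Gimap6 and 0.35 for Mlkl. Adjusted p-values of these 8 genes after Trdn ran from 0.4997 to 0.597. The mean signals of Nr2f1, Speer4a and Nfatc4 lay below the array median of 3.76 in both groups.

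Among genes lower in the arrays labelled RictoraP2KO none passed. The smallest unadjusted p belonged to Tesc, which encodes the calcium-binding protein tescalcin, at 3.65 ± 0.21 (SD, n = 4) against 4.47 ± 0.17 (SD, n = 4), a difference of -0.82 (SE 0.121; limma adjusted p = 0.311). Fdps, which makes farnesyl diphosphate for sterol synthesis, differed by -0.60 (SE 0.113; limma adjusted p = 0.4997), and Paics, an enzyme of purine synthesis, by -0.33 (SE 0.062). Differences were -0.64 for Pnldc1, -0.52 for Mrm1, -0.51 for Gstt3, -0.45 for Nrip2, -0.41 for Cox7a2l, -0.30 for Zdhhc14 and -0.29 for Mroh1. Only 1 of the 2 probe sets of Zdhhc14 had that sign. In each of the 10 genes the values of the groups did not overlap, but selection by small p favours this, so it adds no support.

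**Figure D1:**
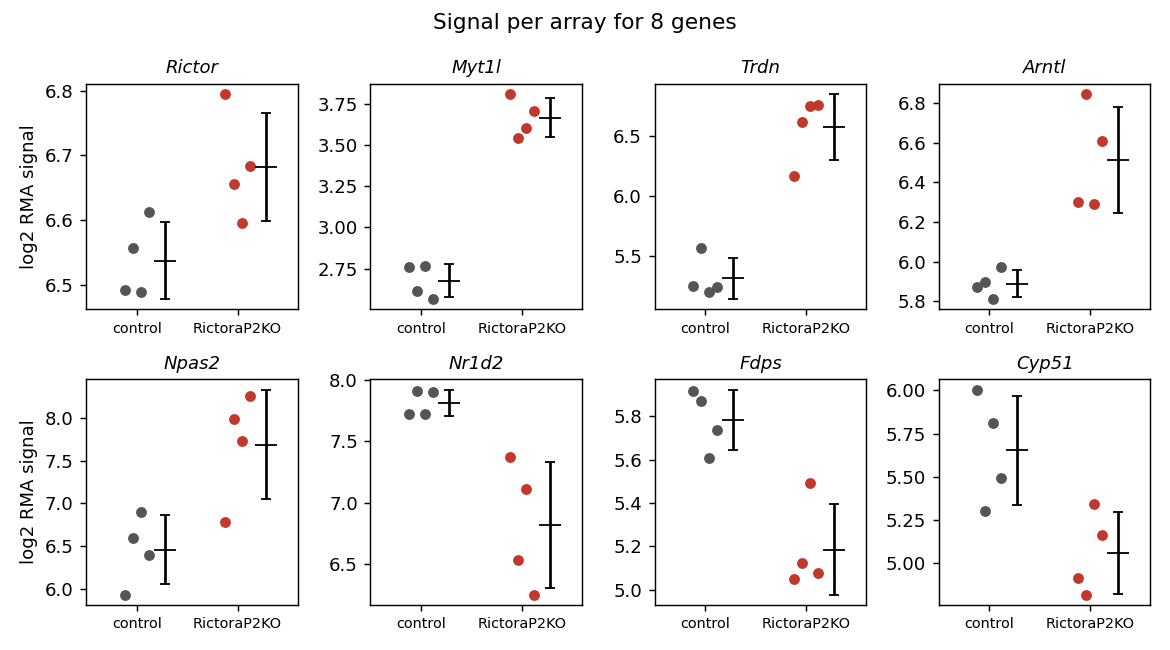
Log2 RMA signal (y axis of each panel, with its own range) of 8 genes in the 4 control arrays (grey) and the 4 arrays labelled RictoraP2KO (red); each point is 1 array and the black bar beside the points is the mean with its SD. Myt1l averages 3.66 against 2.68 and Nr1d2 6.82 against 7.81 with no overlap, whereas the Rictor signals, 6.68 against 6.54 on average, overlap.

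Single genes of the circadian clock had differences of either sign. Higher in the arrays labelled RictoraP2KO were Arntl, which encodes the activator BMAL1 (6.51 ± 0.27 against 5.89 ± 0.07, SD, n = 4; difference 0.62, SE 0.123), and Npas2, its partner and the paralog of Clock (7.69 ± 0.64 against 6.46 ± 0.41, SD, n = 4; difference 1.23, SE 0.317). Lower were Nr1d2, which encodes the repressor REV-ERBβ (6.82 ± 0.51 against 7.81 ± 0.11, SD, n = 4; difference -0.99, SE 0.221), and Bhlhe41, the repressor DEC2 (4.13 ± 0.34 against 4.71 ± 0.20, SD, n = 4; difference -0.58, SE 0.168). Of the 22 measured members, these 4 passed when adjusted over the list alone, 2 higher and 2 lower, and 0 passed when adjusted over all probe sets. Their adjusted p-values over all probe sets ran from 0.524 to 0.649. Unadjusted p-values under 0.05 were also found for Cry1 (0.93, SE 0.331), Nfil3 (0.90, SE 0.311) and Bhlhe40 (-0.74, SE 0.315).

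The other 15 clock genes had unadjusted p-values above 0.05. Clock itself differed by 0.09 (SE 0.080). Among the period genes, Per1 differed by 0.05 (SE 0.282), Per2 by 0.14 (SE 0.304) and Per3 by -0.35 (SE 0.249), and the sign for Per1 and Per2 turned when single arrays were left out. Differences were 0.10 for Rorb, 0.09 for Timeless, 0.09 for Csnk1e, -0.21 for Fbxl21, -0.12 for Arntl2, -0.11 for Tef, -0.10 for Ciart, -0.09 for Rora, -0.07 for Cry2, -0.05 for Hlf and -0.02 for Csnk1d. The list as a whole was not called, with 10 members above and 12 below 0. Its mean difference was 0.04 and its median -0.04, opposite in sign (camera adjusted p = 0.693, 0.596 before adjustment; fry adjusted p = 0.889). Fry's test for change in either direction gave an adjusted p = 0.168 over the 34 lists, 0.0123 before adjustment. Without the 3 arrays that carried signal of another tissue the mean was -0.0087. The 15 genes of the list of clock outputs were not called (camera adjusted p = 0.426); their smallest p-values belonged to Hif3a (0.18), Cdkn1a (0.27) and Usp2 (-0.33), none of which passed.

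**Figure D2:**
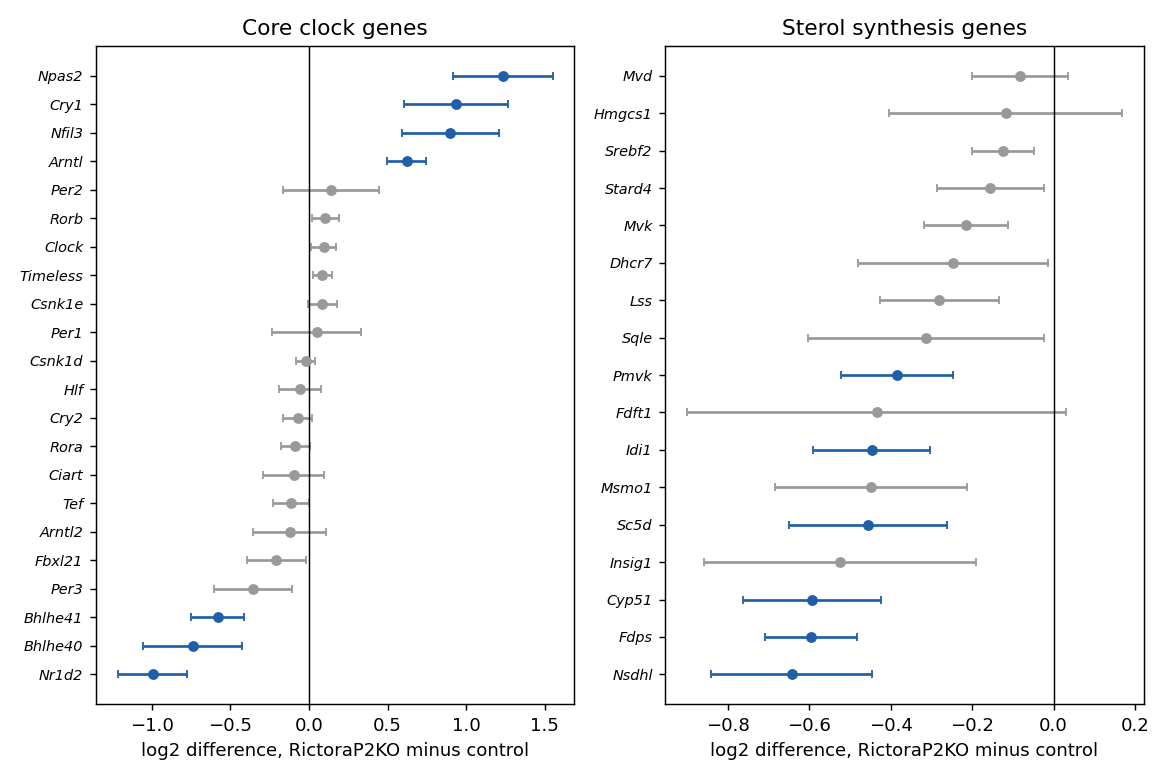
Log2 difference, RictoraP2KO minus control (x axis), of each measured gene of the core clock list (left, 22 genes) and the sterol synthesis list (right, 17 genes); points are differences over 4 and 4 arrays, bars their SE, and blue marks an unadjusted p under 0.05. Clock genes lie on both sides of 0, from Npas2 at 1.23 to Nr1d2 at -0.99, and all 17 sterol genes lie below 0.

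The list of sterol synthesis genes was called lower in the arrays labelled RictoraP2KO. All 17 measured members were lower, with a mean difference of -0.36 and a median of -0.38 (camera adjusted p = 1.35e-07). That call was not kept with a correlation estimated from the arrays (adjusted p = 0.734 with an estimated correlation, 0.0449 before adjustment). Fdps passed when adjusted over the list alone, and 0 members passed over all probe sets. Cyp51, lanosterol demethylase, differed by -0.59 (SE 0.169), and Nsdhl, which acts in later steps of the pathway, by -0.64 (SE 0.198). Per array the list mean ran from 0.04 to 0.42 in the control arrays and from -0.40 to 0.11 in those labelled RictoraP2KO, of which replicate 3 was the highest. An exact two-sided permutation test of these array means gave p = 0.0571. The list was called in each of the 8 omissions of 1 array, with means from -0.45 to -0.28. The 23 genes of fatty acid synthesis were not called (mean -0.13; camera adjusted p = 0.242); the mean was -0.05 without RictoraP2KO replicate 2, and the list was called without RictoraP2KO replicate 3 (-0.20). There, Acss2, which makes acetyl-CoA from acetate, differed by -0.71 (SE 0.210), Srebf1 by 0.30 (SE 0.115) and Mlxipl by -0.25 (SE 0.108), and none passed.

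Of the 34 lists, 11 were called by camera, 9 higher and 2 lower. With an estimated correlation 0 lists were called (smallest adjusted p = 0.734, with 2 lists at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.748, with 1 list at an unadjusted p under 0.05). In the called lists 0 members passed over all probe sets, and apart from Fdps 0 passed when adjusted over the list alone. The values below for single members are therefore differences that did not pass.

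The list of insulin signalling genes was called higher, with 14 of 19 members above 0 and a mean of 0.12 (camera adjusted p = 0.0218; adjusted p = 0.734 with an estimated correlation). Irs2, an adaptor of the insulin receptor, differed by 0.53 (SE 0.178), Pik3r1, the regulatory subunit of PI3 kinase, by 0.52 (SE 0.237) and Insr, the receptor, by 0.19 (SE 0.094). The call was lost without RictoraP2KO replicate 1 (adjusted p = 0.0794), control replicate 1 (0.157) or control replicate 2 (0.0539). Of the 19 targets of FOXO factors, which Akt inhibits, 10 were above 0, and the list was not called (camera adjusted p = 0.320). Irs2 and Insr are in both lists, and Bnip3, the third by p, differed by 0.32.

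Camera called 5 lists of immune genes higher. For macrophage markers 20 of 22 members were above 0 with a mean of 0.24 (camera adjusted p = 5.59e-06; adjusted p = 0.734 with an estimated correlation), with Mrc1 at 0.43 (SE 0.125), Mpeg1 at 0.55 (SE 0.197) and C1qb at 0.37 (SE 0.161). For inflammatory mediators 20 of 24 were above 0 with a mean of 0.16 (camera adjusted p = 0.00377; adjusted p = 0.734 with an estimated correlation), with Tlr4 at 0.28, Ccl8 at 0.58 and Vcam1 at 0.25. Interferon response genes had a mean of 0.09 (19 of 26 above 0; camera adjusted p = 0.0106; adjusted p = 0.734 with an estimated correlation), with Zbp1 at 0.31, Ifih1 at 0.25 and Ifit2 at 0.28. T cell markers had a mean of 0.14 (13 of 15 above 0; camera adjusted p = 0.00701), with Cd4 at 0.36, Lat at 0.40 and Cd5 at 0.21, and B cell markers one of 0.28 (15 of 16 above 0; camera adjusted p = 0.00084), with Blk at 0.21, Cxcr5 at 0.23 and Ighm at 0.91. For both of these, too, adjusted p = 0.734 with an estimated correlation. RictoraP2KO replicate 2 had the highest B cell value, 0.78, where the other arrays lay between -0.38 and 0.14. It also had the highest mean of the lymph node genes, 0.45, where the others reached at most 0.19. Without this array the B cell mean was 0.07, Ighm differed by 0.33 and the B cell call was lost. Without it the calls for inflammatory mediators, interferon response and T cells were lost too, as they were without control replicate 3. The interferon call was also lost without RictoraP2KO replicate 3, and its mean ran from 0.025 without that array to 0.17 without RictoraP2KO replicate 4 or control replicate 4; without control replicate 3 it was 0.025. The T cell mean was 0.06 without RictoraP2KO replicate 2. Without RictoraP2KO replicate 3 the macrophage mean was 0.35 and the B cell mean 0.46. With the 3 arrays that carried signal of another tissue left out, the macrophage mean was 0.09 (camera adjusted p = 0.223) and the interferon mean -0.04. The calls for inflammatory mediators (mean 0.0097) and T cells (0.06) were lost there. The B cell list was still called (mean 0.17, camera adjusted p = 0.00557), although the array means of the groups overlapped. For B cells RictoraP2KO replicates 1, 3 and 4 stood at 0.08, -0.38 and 0.08, and control replicates 1 and 4 at -0.31 and -0.22. Over all arrays an exact two-sided permutation test of the B cell array means gave p = 0.371. The T cell call was also lost without dim probe sets, where its mean was 0.14 (camera adjusted p = 0.483).

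The list of fibroblast and matrix genes was called higher by a mean of 0.15, with 25 of 27 members above 0 (camera adjusted p = 5.96e-06; adjusted p = 0.734 with an estimated correlation). Their smallest p-values belonged to the collagen genes Col4a1 (0.32, SE 0.072) and Col1a1 (0.33, SE 0.109) and to Postn, which encodes periostin (0.29, SE 0.097). Without RictoraP2KO replicate 1 the mean was 0.09, and without the 3 arrays 0.08 (camera adjusted p = 0.0360). Endothelial markers had a mean of 0.07 with 12 of 17 above 0 (camera adjusted p = 0.0278; adjusted p = 0.734 with an estimated correlation), and the VEGF receptor gene Kdr differed by 0.24, Emcn by 0.17 and Cdh5 by 0.10. This call was lost in 4 of the 8 omissions of 1 array, those of replicates 1 and 2 of each group, with array weights and without the 3 arrays (mean 0.03). Its mean was 0.02 without RictoraP2KO replicate 2 and 0.14 without RictoraP2KO replicate 3. Amino acid and unfolded protein stress genes had a mean of 0.26 and a median of 0.09, with 13 of 17 above 0 (camera adjusted p = 0.0215; adjusted p = 0.734 with an estimated correlation). Sesn2 differed by 0.73, Chac1 by 0.96 and Asns, asparagine synthetase, by 0.28. Without RictoraP2KO replicate 2 the mean of this list was 0.11 and the call was lost, as it was with array weights and without the 3 arrays (mean 0.12).

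Neuron markers were lower in the arrays labelled RictoraP2KO, with all 15 below 0 and a mean of -0.39 (camera adjusted p = 0.00311; adjusted p = 0.734 with an estimated correlation). Nefm differed by -0.20, Chga by -0.25 and Elavl4 by -0.12. This value rested on 1 array. Control replicate 3 stood at 1.24 and the other 7 arrays between -0.29 and -0.10, and without it the mean was -0.04 and the call was lost, as it was without the 3 arrays (mean -0.09) and without dim probe sets (-0.51). Signal of other tissues was also uneven between the arrays. Lung epithelial markers, listed after the values were seen, stood at 2.84 in control replicate 2 and between -0.51 and -0.33 in the other 7. Skeletal muscle markers stood at 1.09 in RictoraP2KO replicate 2 and between -0.32 and -0.01 in the others. Cardiac muscle markers ran from -1.11 in RictoraP2KO replicate 1 to 1.45 in RictoraP2KO replicate 2. They stood at 0.33 in control replicate 1, so the arrays kept when the 3 were left out were uneven too.

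**Figure D3:**
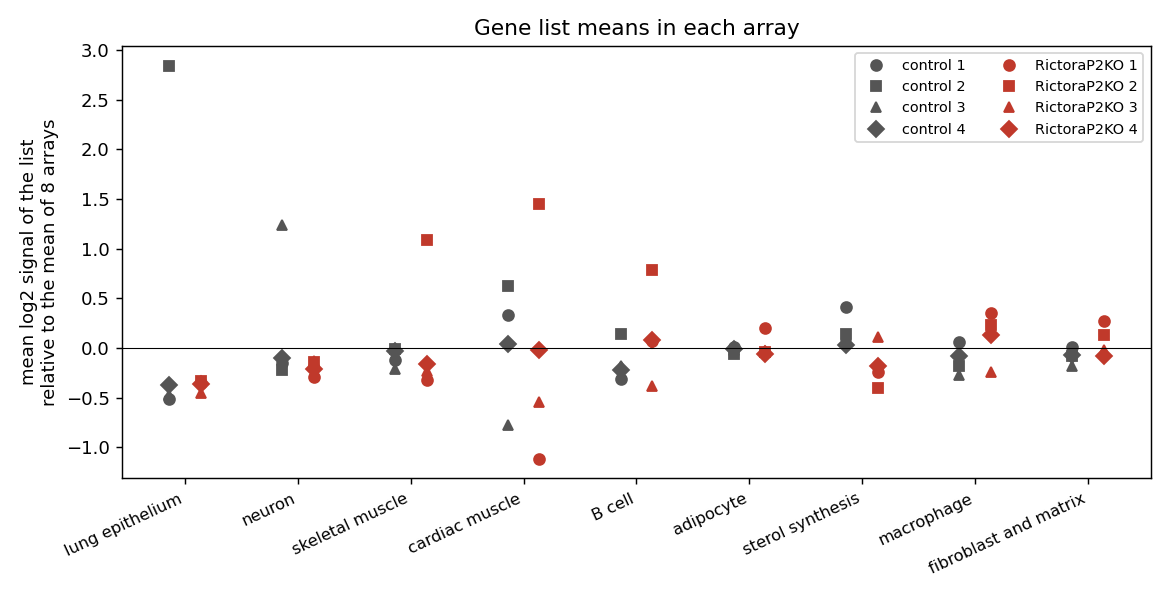
Mean log2 signal of 9 gene lists relative to the mean of the 8 arrays (y axis) in each array; grey marks control arrays, red those labelled RictoraP2KO, and the marker shape gives the replicate. Single arrays stand apart for lung epithelium (control 2 at 2.84), neuron (control 3 at 1.24) and skeletal muscle (RictoraP2KO 2 at 1.09), while the sterol synthesis means run from -0.40 to 0.42.

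Fat cell and energy genes were not called. The mean of 14 adipocyte markers differed by 0.04, with an interval from -0.11 to 0.19 (camera adjusted p = 0.520), and by -0.02 without RictoraP2KO replicate 1. Pparg, the regulator of fat cell differentiation, differed by -0.21 (SE 0.114), Lpl by 0.11 and Pnpla2 by 0.04. The 22 brown fat and thermogenic genes had a mean of -0.08 (camera adjusted p = 0.328), or 0.03 without RictoraP2KO replicate 1, with Cox7a1 at -0.13, Esrra at -0.19 and Ppara at -0.27. The 18 genes of fatty acid oxidation had a mean of -0.04 (camera adjusted p = 0.391), or 0.0075 without the same array, with Fabp3 at -0.60, Acadm at -0.09 and Acads at -0.15. The 28 genes of oxidative phosphorylation had a mean of -0.0041 (camera adjusted p = 0.987), above 0 without RictoraP2KO replicate 2 (0.02) or 4 (0.0077) or control replicate 2 (0.01) or 4 (0.0018), with Cycs at 0.18, Ndufb3 at -0.12 and Ndufa1 at 0.15; 2 of the 3 Cycs probe sets had its sign. The 30 vasoactive genes, which regulate vessel tone, had a mean of 0.09 (camera adjusted p = 0.161), and were called without RictoraP2KO replicate 3 (0.15). Adm, the vasodilator adrenomedullin, differed by 0.51 (SE 0.192), Agtr1a, the angiotensin receptor, by 0.22 (SE 0.089) and Rbp4 by -0.66 (SE 0.273), and none passed.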

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

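In this part all tests of explanations were chosen after the values had been seen, except the counts over splits of the arrays, which were written before they were run; the statistics those splits used for the clock genes in either direction and for the sterol genes were chosen after the pattern was seen. A single array stood far from the other 3 of its group in 22 of the 342 groups of 4 values examined, where chance gives about 1 in 20, or 17.1.

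For gene lists, the array that stood apart was RictoraP2KO replicate 2 for skeletal muscle (1.09, the others of its group at most -0.16), control replicate 3 for neurons (1.24, the others at most -0.10), control replicate 2 for lung epithelium (2.84, the others at most -0.37) and RictoraP2KO replicate 1 for adipocytes (0.20, the others at most -0.03). For genes it was control replicate 2 for Trdn (5.57) and control replicate 1 for Kdr (6.997) and Gldn (6.16). It was control replicate 3 for Acss2 (7.89) and Gadd45b (4.57), and control replicate 4 for Fosb (5.94) and Zbtb16 (8.71). In the arrays labelled RictoraP2KO it was replicate 1 for Fosb (5.28), replicate 2 for Ciart (4.90), Ndufa1 (7.72), Ifit2 (4.34) and Glycam1 (3.09), replicate 3 for Mrm1 (4.78), Fdps (5.49), Csnk1e (7.23), Hif3a (2.46) and C1qb (8.31), and replicate 4 for Tesc (3.34).

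Of the 22 clock genes measured, 4 passed when adjusted over the list alone, 2 higher and 2 lower. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave a fry p for either direction as small as 0.0123 (smallest of the other splits 0.0257), but the statistic was picked after the pattern was seen and its adjusted p over the 34 lists was 0.168, so chance is not excluded; for the mean shift of the list 22 of 35 splits gave a camera p as small as 0.596 (smallest of the others 0.00771), and chance cannot be excluded there either. Signal of another tissue in 3 arrays stays open: without them the median size of the differences of the 22 genes was 0.172, against 0.118 with all arrays, but only 18 kept their direction and mixed splits of the 5 arrays left gave 0.136 to 0.222. A difference in the hour of dissection cannot be told apart from a clock shifted by the genotype, since either would move these genes and the labels give both groups the same hour; the contrast of genes that peak with or after Bmal1 with those driven by E-boxes (exact two-sided permutation p = 0.0286) decides nothing, because its members were chosen with their values known. A glucocorticoid or handling difference stays open too, since the glucocorticoid list differed by 0.10 with an interval from -0.34 to 0.54 (exact two-sided permutation p = 0.543), from -0.01 without RictoraP2KO replicate 4 to 0.25 without RictoraP2KO replicate 3.

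The sterol synthesis list was called lower in the arrays labelled RictoraP2KO, but not by camera with an estimated correlation (adjusted p = 0.734). In 2 of the 35 splits the mean difference of the list lay as far from 0 as the real 0.357 (largest of the others 0.395), so chance cannot be excluded. For a lower share of fat cells, the list of general adipocyte markers differed by 0.038, with an interval from -0.11 to 0.19. Without RictoraP2KO replicate 1 the adipocyte list differed by -0.02 (interval from -0.07 to 0.03). These intervals lie above the sterol difference of -0.36, which argues against a fall of that size in these markers. The sterol list's own interval, from -0.69 to -0.03, overlaps them, so a smaller fall in the share of fat cells stays open. The brown fat and thermogenic list differed by -0.08, with an interval from -0.41 to 0.26 that holds the sterol difference. A lower share of brown fat cells therefore stays open. Signal of another tissue in 3 arrays stays open: the mean was -0.33 without them, but with an interval from -0.97 to 0.31. Chance, an effect of the genotype and, untested for these genes, the hour of dissection or handling stay open.

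Myt1l was the 1 gene past the threshold. In 2 of the 35 splits as many probe sets passed (1 in the real split, 1 at most in the others), so chance cannot be excluded. Targeted mice can carry DNA of another strain or an inserted transgene. A long differing stretch of chromosome 12, where Myt1l lies in the RefSeq annotation of assembly GRCm38.p6, was therefore tested. Genes there showed no excess: 3, or 0.502%, had an unadjusted p under 0.01, against 1.21% elsewhere (one-sided Fisher's exact p = 0.975). This count would miss a stretch in which few genes changed expression, so a long stretch stays open. A short stretch near Myt1l cannot be told apart from an effect on this gene alone, since 1 of the 100 nearest genes, Pqlc3 (-0.49), had such a p, as did 1 or more in 24 of the 35 splits (at most 7). Pqlc3 was named after its value was seen.

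The number of called lists did not separate the groups. In 16 of the 35 splits camera called at least the 11 lists of the real split, and at most 20, so chance cannot be excluded, and camera at the preset correlation called lists in mixed splits of this tissue too.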

How the results depend on the processing

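The joint omission of 3 arrays was chosen after the data were seen; the other alternatives were fixed before the data were examined. Myt1l passed in the main test, and 1 probe set also passed with quantile normalisation once more, median centring, limma-trend, robust eBayes, array weights, an adjusted p under 0.1, the added 1.5-fold limit, or only probe sets with 1 symbol. The first pair could move almost nothing, since the arrays already had equal distributions. The count was 0 without dim probe sets (Myt1l is below that limit), 0 with an unmoderated test and 0 without the 3 arrays, where fewer arrays were tested. It was 0 to 5 when 1 array was left out, with 5 only without RictoraP2KO replicate 1, and 55 at an unadjusted p under 0.01 with a 1.5-fold difference (26 higher, 29 lower). With the replicate block 0 probe sets and 11 lists were called. Same-numbered arrays did not deviate together (correlations from -0.15 to 0.09, and 0 of 4 arrays correlated best with their own number), so the numbers were not taken to pair the arrays.

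The Rictor difference kept its sign throughout, from 0.11 to 0.17 when 1 array was left out. The count of lists was 11, between 9 and 11 in the other settings that kept camera at the preset correlation and all arrays, 0 with an estimated correlation and 0 with fry. It was 7 to 14 when 1 array was left out, with 7 without control replicate 3. Without the 3 arrays 9 lists were called, of which 4 were among the 11; the other 5 were smooth muscle (-0.26), skeletal muscle (-0.17, against 0.19 with all arrays), cardiac muscle (-0.74), mesothelium (0.21, against -0.02) and immediate-early genes (-0.27). Lists called only with 1 array left out were fatty acid synthesis (-0.20), vasoactive genes (0.15) and glucocorticoid response (0.25), all without RictoraP2KO replicate 3, and cell cycle (0.07) without control replicate 1. Sterol synthesis, macrophage and fibroblast lists were called in each omission of 1 array. Exact two-sided permutation tests of their array means, over all arrays, gave p = 0.0571, 0.143 and 0.171 in that order. The mean of the core clock list ran from 0.0094 to 0.068 in these and turned to -0.0087 without the 3 arrays; the cause was not tested.

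Of 135 named gene results, 128 kept their direction whenever 1 array was left out. The other 7 ran from -0.29 to 0.081 (Arntl2), -0.32 to 0.0034 (Ciart), -0.13 to 0.41 (Per2), -0.16 to 0.015 (Hlf), -0.049 to 0.022 (Csnk1d), -0.13 to 0.33 (Per1) and -0.23 to 0.15 (Bpgm). With array weights Per1 stood at -0.012. Without the 3 arrays the sign turned for the interferon list (-0.044), Fbxl21 (0.019), Arntl2 (0.19), Per2 (-0.17), Csnk1d (0.014), Glycam1 (-0.0037), Nppb (-0.092) and Bpgm (0.29). The cause was not tested. Signal near the floor of the array, as for Myt1l, limits how far a fold can be read. Among the named T cell, B cell and neuron markers, Cd4, Cd5, Lat, Blk, Cxcr5, Nefm, Chga and Elavl4 also had mean signals below the array median of 3.76 in both groups.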

Other observations

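The gene groups of the first 3 paragraphs were fixed before the data were examined, and no member passed when adjusted over all probe sets. Immediate-early genes, which respond within minutes to stimulation, had a mean difference of -0.17 over 24 members (17 below 0; camera adjusted p = 0.313). Fosb was lower in the arrays labelled RictoraP2KO, at 4.48 ± 0.54 (SD, n = 4) against 5.60 ± 0.22 (SD, n = 4), a difference of -1.13 (SE 0.247; limma adjusted p = 0.605). It passed when adjusted over the list alone, where 1 member passed and was lower, and over all probe sets without RictoraP2KO replicate 1 (limma adjusted p = 0.0234). Gadd45b differed by -1.36 (SE 0.412) and Klf2 by 0.29 (SE 0.150). Schwann cell markers had a mean of -0.16 over 11 members (camera adjusted p = 0.389). S100b differed by -1.0 (SE 0.340), Gldn by -0.78 (SE 0.330) and Cldn19 by -0.22 (SE 0.064). Without control replicate 1 the Schwann cell mean was -0.11 and Gldn differed by -0.45, and without the 3 arrays the mean was -0.27. Smooth muscle markers had a mean of -0.15 over 14 members, 12 of them below 0 (camera adjusted p = 0.192), with Npnt at -0.78, Actg2 at -0.32 and Myh11 at -0.27. With arrays left out, the immediate-early list was called lower without RictoraP2KO replicate 2 (-0.24), control replicate 1 (-0.27) or the 3 arrays with signal of another tissue (-0.27), and smooth muscle without RictoraP2KO replicate 2 (-0.24), control replicate 2 (-0.21) or the 3 arrays (-0.26); the means were nearer 0 for the immediate-early list without RictoraP2KO replicate 3 (-0.01) or control replicate 4 (-0.06) and for smooth muscle without RictoraP2KO replicate 1 (-0.07).

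Genes listed beforehand as neighbours of Rictor, which lies on chromosome 15 (RefSeq, GRCm38.p6), had a mean of 0.05 over 14 members (camera adjusted p = 0.328). That mean ran from 0.016 without control replicate 1 to 0.08 without control replicate 4. Fyb differed by 0.45, Dab2 by 0.26 and Osmr by 0.25, and these 3 of the 14 had an unadjusted limma p under 0.05. Across the array 2062 of 28371 probe sets did. Whether a stretch of DNA near Rictor differs between the groups was not tested. The glucocorticoid list, of 17 members, had a mean of 0.10 (camera adjusted p = 0.238), was called without RictoraP2KO replicate 3 (0.25) and stood at -0.01 without RictoraP2KO replicate 4, with Hif3a at 0.18, Angptl4 at -0.28 and Zbtb16 at 0.70. Heat shock genes had a mean of -0.0064 over 14 members and a median of 0.0085, opposite in sign (camera adjusted p = 0.782), and a mean above 0 without RictoraP2KO replicate 1 (0.05) or 3 (0.0043) or control replicate 1 (0.07), with Hspe1 at 0.26, Hspa8 at -0.24 and Dnajb1 at -0.20. Cell cycle genes had a mean of 0.04 over 26 members (camera adjusted p = 0.242), called without control replicate 1 (0.07) and below 0 without the 3 arrays with signal of another tissue (-0.02), with Mki67 at 0.45, Cdkn3 at -0.19 and Mcm2 at 0.16. Thymocyte genes had a mean of 0.03 over 9 members (camera adjusted p = 0.389, fry p for either direction 0.00178, adjusted 0.0606). Their mean ran from 0.0061 without control replicate 3 to 0.05 without control replicate 2. Ccr9 differed by 0.26, Rag2 by -0.11 and Bcl11b by 0.11, all at signals under 3.

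Lists for other tissues were not called with all arrays, but some were with arrays left out. Skeletal muscle genes had a mean of 0.19 over 20 members (camera adjusted p = 0.238), with Myl1 at -0.43, Pvalb at 0.52 and Myh7 at -0.16. The list was called without RictoraP2KO replicate 1 (0.33) or 3 (0.30) and, lower, without replicate 2 (-0.15) or the 3 arrays with signal of another tissue (-0.17). Without RictoraP2KO replicate 2 Pvalb differed by 0.07, while Trdn still differed by 1.24. Cardiac muscle genes had a mean of -0.11 over 10 members (camera adjusted p = 0.693), with Sln at -0.19, Ryr2 at -0.60 and Nppb at 0.16; the list was called lower without RictoraP2KO replicate 2 (-0.61) and without the 3 arrays (-0.74), and was above 0 without RictoraP2KO replicate 1 (0.24) or 3 (0.05) or control replicate 2 (0.08). Mesothelial genes had a mean of -0.02 over 11 members (camera adjusted p = 0.789), with Krt18 at -0.33, Lrrn4 at 0.16 and Upk3b at 0.17, and the list was called higher without the 3 arrays (0.21) and was also above 0 without RictoraP2KO replicate 2 (0.09) or 4 (0.03) or control replicate 3 (0.12). Erythroid genes had a mean of 0.04 over 4 members (camera adjusted p = 0.9503), 0.25 without control replicate 3 and below 0 without RictoraP2KO replicate 1 (-0.02) or control replicate 1 (-0.09) or 4 (-0.0088), with Epb42 at -0.09, Slc4a1 at 0.22 and Bpgm at -0.08. Lymph node genes had a mean of 0.14 over 7 members (camera adjusted p = 0.238), with Ccl19 at 0.28, Clu at 0.22 and Glycam1 at 0.23; without RictoraP2KO replicate 2 the mean was 0.01 and these genes stood at 0.10, 0.13 and 0.0046.

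The 3 lists added after the values were seen were adjusted among themselves. The 5 clock genes that peak with or after Bmal1 had a mean of 0.76 (camera adjusted p = 7.99e-07; adjusted p = 0.0453 with an estimated correlation), and the 8 driven by E-boxes one of -0.25 (camera adjusted p = 0.0168; adjusted p = 0.0591 with an estimated correlation). Since their members were chosen with the values known, these are no independent evidence. The 13 lung epithelial genes had a mean of -0.75 (camera adjusted p = 0.0389, and 0.496 with an estimated correlation). This mean rested on control replicate 2, at 2.84, with the other arrays between -0.51 and -0.33. An exact two-sided permutation test of the array means gave p = 0.971. In control replicate 2 the surfactant genes Sftpc and Sftpb stood at 9.20 and 7.07, and in the other 7 arrays Sftpc lay between 1.77 and 1.92 and Sftpb between 2.43 and 2.75. Cyp2f2 of that list had signals from 5.89 to 8.37 over the 8 arrays.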
